A study of Rhipicephalus microplus with 8 samples.

How the data were processed

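Transcript levels were measured on 8 two-colour arrays of whole ticks of Rhipicephalus microplus, the cattle tick. Of these, 4 arrays held larvae collected on day 4 after infestation of cattle and 4 held nymphs collected on day 7. Each stage had 2 biological replicates, and each replicate was hybridised on 2 arrays. On every array the tick RNA carried Cy5, and a common reference pool of several life stages and adult female tissues carried Cy3, per the labels. No dye swap was used. A dye bias of a probe cancels in the difference between stages only where it is equal on all arrays. A bias that varies with intensity or between arrays would not cancel, and it could not be examined here.

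The deposited value table holds 1 log2 ratio of sample over reference for each of 13459 array features and each array, with 0 missing values. The authors also deposited 7 tables of their own comparisons, each listing 13459 probes with a log2 fold change, a signed linear fold change and an adjusted p-value, per the file headers. One table adds the unadjusted p-value. Its adjusted values differed from a Benjamini-Hochberg adjustment over the listed probes by at most 4.57% of their size. Fold changes and p-values were given for 10695 probes, and 2764 probes had none in any table. The submitters' processing notes name limma. The scanner, background correction, within-array normalisation and spot filter are not given in the sources used here. Spot intensities were not analysed here, so the signal over background of a feature is unknown. The small number of arrays and of biological replicates limits the precision.

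The value table identifies its rows by feature number and the comparison tables by probe, with no column in common. The rows were therefore joined by value. A probe was assigned to a feature when its deposited larvae against nymph log2 fold change equalled, within 1.2e-09, the plain mean of some larva arrays minus the plain mean of some nymph arrays of exactly 1 feature. This joined 10684 of the 10695 probes, 6516 of them with all 8 arrays and 4168 with fewer. After the fold changes had been moved by 1e-05, 2e-05 or 5e-05, between 21 and 29 probes found a match by chance. The join shows 3 things about the deposited fold changes. They are larvae minus nymphs. They weight all arrays used for a probe equally, technical repeats included. Between 589 and 1497 joined probes per array were computed without that array, which is read here as the authors having left out that spot. The comparison tables are additive to within 4.8e-08 on the log2 scale, as fold changes from one model of 5 groups would be.

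Probes are named by contig or expressed sequence tag, and the files do not pair these with genes. None of the names matched the reference gene table of the USDA_Rmic assembly (0 matches), so no genome position is given. Only 4 contig names carry a gene word. The 25 gene lists that had been fixed as keywords on probe descriptions, cell type marker lists included, could not be tested, and no pathway or cell type is reported. The rule for named transcripts, fixed before the data were examined, then allows at most 2 identifiers higher and 2 lower per comparison. For the stage comparison these are the transcripts with the largest differences among those past the threshold, with every larva array on the same side of every nymph array. For both stages against the coded groups, they are those with the largest smallest fold among the 6 tables concerned. The 4 contigs with a gene word were added after their values were seen.

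Technical repeats were averaged first, leaving 2 biological replicates per stage. The stage difference was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design fixed before the data were examined uses all 13459 features. After the data were seen, a second fit was added on the authors' probes: the 9562 joined features for which every biological replicate keeps at least 1 array that the authors used, with the arrays they left out set missing. The other 1122 joined features had a biological replicate with no such array. Labels describe the biological replicates only as such, so p-values measure the spread between these samples. A two-sided exact permutation test of 2 against 2 cannot go below 0.333, so single transcripts were tested only in the model over all features. The script was tested on simulated data for the 13459 features with 200 changed. It recovered 8% of the changes of 1 on the log2 scale and 100% of those of 2, 3 and 4, with 12 false calls.

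The labels number the biological replicates 1 and 2 in both stages without tying equal numbers together, and the block on the number is given as an alternative only. Other alternatives were the treatment of technical repeats, centring or quantile normalisation between arrays, robust variance moderation, stricter thresholds, the mean of probes named A and B of a contig number and leaving out each biological replicate. Filters and variance trends on mean intensity could not be run, and a rule for missing values had nothing to act on. The authors' comparisons with 3 groups coded G, O and S are reported as deposited, since arrays of those groups were not analysed here. To judge overlaps between tables that share arrays, 5 unchanged groups of 4 arrays were simulated for 10695 probes from the observed deviations within stages, and fitted with all arrays as independent. Summaries and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.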

Results

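The series compared the transcriptomes of feeding immature stages of the cattle tick Rhipicephalus microplus, a one-host tick whose larvae, nymphs and adults feed on the same animal. Whole larvae of day 4 and whole nymphs of day 7 after infestation, of mixed sex and the Mozambique strain, were each hybridised against a common reference pool. The pool mixed adult tissues of day 20 with whole ticks collected on days 4, 5, 7, 13 and 15. Each stage had 2 biological replicates with 2 technical repeats each, giving 8 arrays. The authors' deposited tables further compared both stages with 3 groups coded G, O and S, whose codes the labels do not spell out.

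Larvae and nymphs differed by more than the replicates of either stage did. Among the 6516 transcripts that the authors used on all 8 arrays, technical repeats of larvae correlated at r = 0.984 and 0.964 across probes, and those of nymphs at 0.873 and 0.916. The biological replicates correlated at 0.925 in larvae and 0.850 in nymphs. Between the stages, the 4 pairings of replicates gave r between 0.475 and 0.594. The SD of the log2 differences was 0.391 between larva replicates, 0.515 between nymph replicates and between 0.886 and 0.983 across stages. These are correlations across probes, which are not independent replicates. Whether the spread differed between the stages was not tested.

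The first comparison asked which transcripts differ between feeding larvae and nymphs. Contig2248 and Contig4725 were the named transcripts highest in larvae relative to nymphs, and Contig571 and Contig4035 those highest in nymphs. Contig2248 stood at a log2 ratio to the pool of 3.07 ± 0.33 in larvae and -3.57 ± 0.20 in nymphs (SD, n = 2), a 99.7-fold difference (limma, log2 difference 6.64, SE 0.28, adjusted p = 0.00128). Contig4725 reached 2.63 ± 0.07 in larvae and -3.72 ± 0.35 in nymphs, or 82.0-fold (limma, log2 difference 6.36, SE 0.27, adjusted p = 0.00128). In the other direction, Contig571 stood at -2.68 ± 0.28 in larvae and 4.17 ± 0.21 in nymphs, 115-fold higher in nymphs (limma, log2 difference -6.85, SE 0.27, adjusted p = 0.00128). Contig4035 stood at -1.91 ± 0.50 in larvae and 4.60 ± 0.31 in nymphs, 91.5-fold higher in nymphs (limma, log2 difference -6.52, SE 0.33, adjusted p = 0.00136). Every larva array lay on one side of every nymph array for these 4 transcripts. The authors used all 8 arrays for Contig2248 and Contig571, 7 for Contig4035 and 6 for Contig4725. Both arrays they left out for Contig4725 were those of larva replicate 1, so its larva mean, SD and adjusted p rest in part on a biological replicate that the deposited value does not use. Without that replicate its log2 difference was 6.41 (limma, adjusted p = 0.00385). In the authors' deposited table the log2 fold changes of the 4 were 6.64, 6.41, -6.85 and -6.45 in the order named here.

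**Figure D1:**
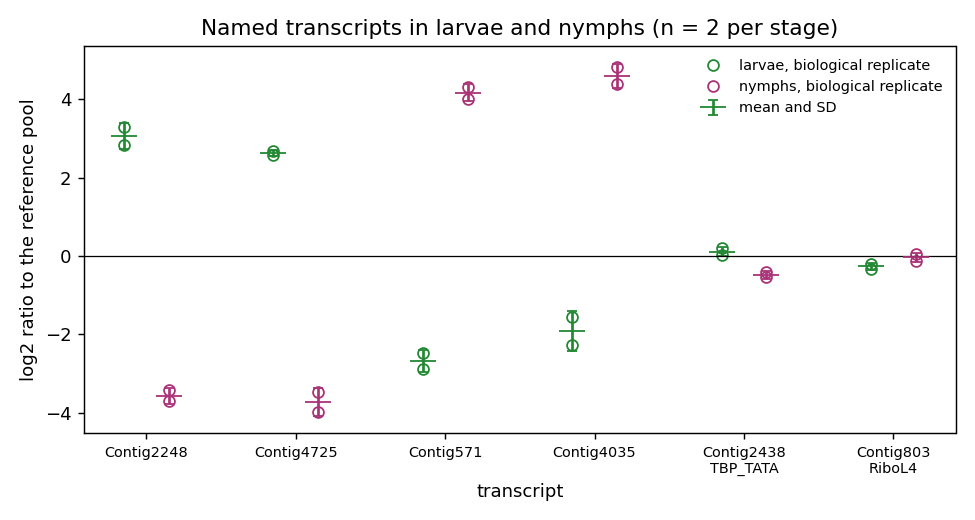
Log2 ratio to the reference pool (vertical axis) of the 4 named transcripts and the 2 contigs with a gene word in their name that have deposited fold changes (horizontal axis), in larvae and nymphs. Open circles are biological replicates, each the mean of 2 arrays, and bars show the mean and SD of n = 2; Contig571 stands at -2.68 in larvae and 4.17 in nymphs, while Contig803_RiboL4 stands at -0.26 and -0.04.

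Among the probes for which the authors gave fold changes, transcripts higher in larvae and transcripts higher in nymphs were about equal in number. This held with all replicates and with the ratios as deposited. Of the 9562 such probes fitted, 1049 passed an adjusted p of 0.05 in limma, 513 higher in larvae and 536 higher in nymphs. With each array centred on its median, the counts on these probes were 443 and 584. With quantile normalisation between arrays, they were 524 and 625. The called transcripts differed by a median of 1.62 on the log2 scale and by at least 0.88, and the median standard error over all fitted probes was 0.25. At least a 2-fold difference was seen for 494 of those higher in larvae and 498 of those higher in nymphs. At least an 8-fold difference was seen for 91 and 49 of them. The authors' deposited table had 4729 of 10695 probes past its adjusted p, 2425 higher in larvae and 2304 higher in nymphs. Of the 9562 probes fitted here, 4384 were past the authors' adjusted p. These included 1048 of the 1049 transcripts, all 1048 with the same sign. Both fits use the same arrays with the same spots left out, so this overlap was largely fixed in advance and is not independent support. The count of 1049 depended on single replicates. It was 171 without larva replicate 1 (105 higher in larvae and 66 in nymphs), 169 without larva replicate 2 (87 and 82) and 2739 without nymph replicate 2 (1291 and 1448).

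Over all 13459 array features, the fit fixed in advance called 3793 features in limma, 3002 higher in larvae and 791 higher in nymphs. Most of the excess on the larval side lay among the 2775 features that could not be joined to a deposited fold change. These had a median larvae minus nymph difference of 1.94 on the log2 scale (quartiles 1.22 and 2.61), against 0.04 for the 10684 joined features. They accounted for 2114 of the calls, 2088 of them higher in larvae. Among the joined features, 914 calls were higher in larvae and 765 higher in nymphs in this fit. The median over joined and other features together was 0.23. With each array centred on its median, 2375 features were higher in larvae and 1579 higher in nymphs. With quantile normalisation between arrays, the counts were 1746 and 1510. The number higher in nymphs was 374 without larva replicate 1 and 415 without larva replicate 2.

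**Figure D2:**
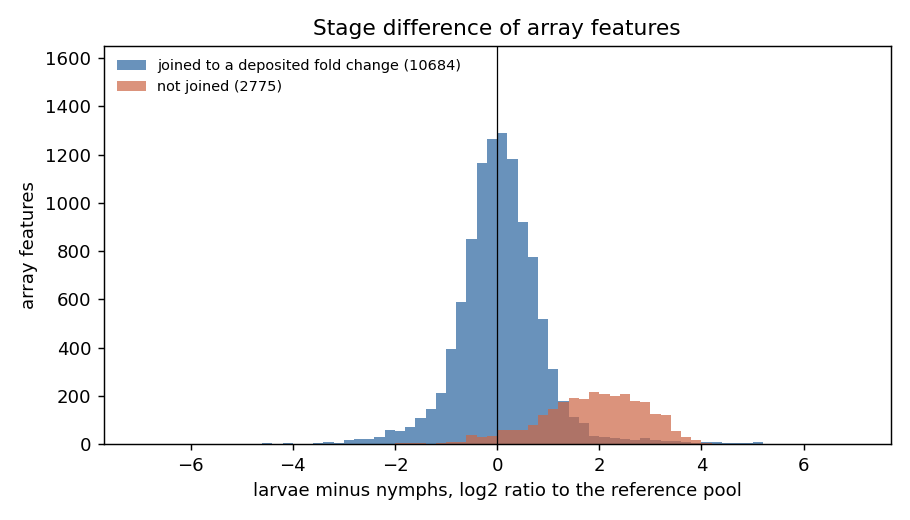
Number of array features (vertical axis) by the mean log2 ratio of the 4 larva arrays minus that of the 4 nymph arrays (horizontal axis), for the 10684 features joined to a deposited fold change and the 2775 not joined. The joined features centre near 0, with a median of 0.04, and the others lie to the right, with a median of 1.94.

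The names of 4 contigs carry a gene word: TBP_TATA, after the TATA-binding protein of the general transcription machinery, RiboL4, EF1a and His3A. Contig2438_TBP_TATA stood at 0.11 ± 0.12 in larvae and -0.48 ± 0.09 in nymphs (SD, n = 2), a log2 difference of 0.60 that did not pass the test (limma, SE 0.24, adjusted p = 0.117). In the authors' deposited table its log2 fold change was 0.68, with an adjusted p of 0.000564. Contig803_RiboL4 stood at -0.26 ± 0.10 in larvae and -0.04 ± 0.12 in nymphs, a log2 difference of -0.23 that did not pass either (limma, SE 0.24, adjusted p = 0.511). The authors' deposited table gives it an adjusted p of 0.0980. The contigs with EF1a and His3A in their names have no deposited fold change.

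The second set of comparisons set larvae and nymphs against the groups coded G, O and S, and is given as the authors' values. The series' design text speaks of tissues and of tissue collection on day 20, so these groups are probably dissected adult tissues, although no label ties the codes to them. The distances would then set whole bodies against single tissues. Transcript levels of both stages lay farthest from group O and nearest to group S. In the authors' deposited tables, the SD of the log2 fold changes over 10695 probes was 1.59 between larvae and O, 1.24 between larvae and G and 1.06 between larvae and S. For nymphs the values were 1.56, 1.09 and 0.94. Between larvae and nymphs the SD was 0.90. Of the 10695 probes, 71.5% passed the authors' adjusted p of 0.05 between larvae and O and 73.2% between O and nymphs. The share was 60.1% between larvae and G and 56.1% between G and nymphs. It was 52.0% between larvae and S, 49.3% between S and nymphs and 44.2% between larvae and nymphs. In the authors' deposited table, 2628 probes past the threshold were at least 2-fold higher in larvae than in O and 2113 at least 2-fold higher in O. Differences between these shares were not tested.

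**Figure D3:**
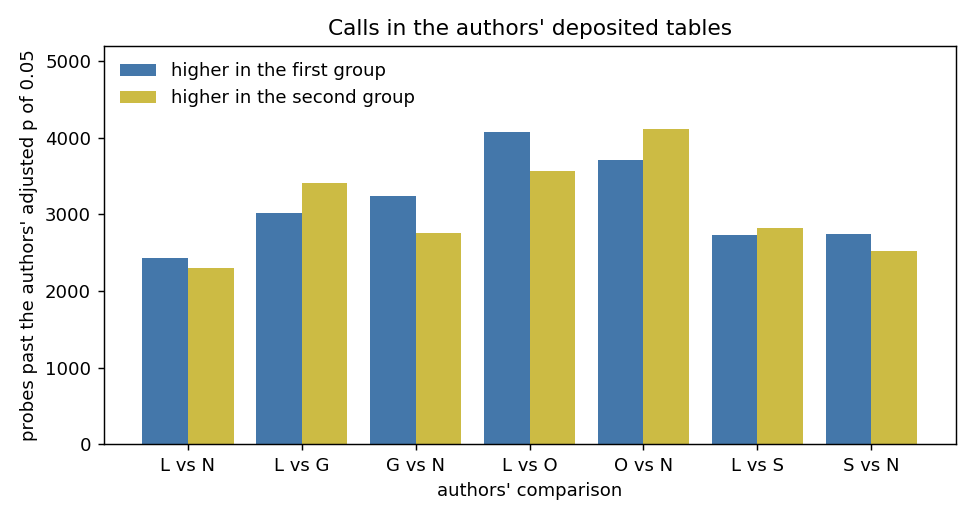
Number of probes past the authors' adjusted p of 0.05 (vertical axis) in each of the 7 deposited comparisons (horizontal axis), split by the group in which the level was higher. L is larvae, N is nymphs and G, O and S are coded groups; the bars of the comparisons with O reach 4076 and 4119 probes and those of larvae against nymphs 2425 and 2304.

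Some transcripts were set apart from all 3 coded groups in both immature stages. If those groups are dissected adult tissues, these sets too compare whole bodies with single tissues. Stage and tissue content then cannot be told apart. In the authors' deposited tables, Contig1924 and Contig6567 had the highest levels in both stages relative to all 3 coded groups, by at least 30.3-fold and 30.1-fold, with adjusted p of at most 1.19e-13 and 2.71e-13. Contig1924 did not differ past the threshold between the stages, with a log2 fold change of 0.27 and an adjusted p of 0.178 in the authors' deposited table. Contig6567 was 2.30-fold higher in larvae than in nymphs, with an adjusted p of 0.000103 in the authors' deposited table. In the same deposited tables of the authors, CV443795 and Contig6867 had the lowest levels, at least 7.37-fold and 6.12-fold lower in both stages than in every coded group, with adjusted p of at most 3.72e-08 and 4.09e-08. The authors' deposited tables placed 667 transcripts higher in both stages than in all 3 groups, 270 of them at least 2-fold in each of the 6 comparisons. Another 691 were lower in both stages in the authors' deposited tables, 73 of them at least 2-fold. The deposited larvae against nymph fold changes weight technical repeats like independent arrays. If the deposited p-values do so too, they measure the spread between arrays, not that between the 2 biological replicates per stage. This limit applies to every p-value and count taken from the authors' tables.

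Other transcripts were set apart in 1 stage. In the authors' deposited tables, 1018 transcripts were higher in larvae than in nymphs and all 3 coded groups, and 712 were higher in nymphs than in all others. At least 2-fold in every comparison were 408 of the former and 290 of the latter. Lower than in all others in the authors' deposited tables were 553 transcripts in larvae and 474 in nymphs, and 46 and 63 of these were at least 2-fold lower in every comparison. The fit of biological replicates, which covers larvae against nymphs only, called 362 of the 1018 and 267 of the 712 higher transcripts. Of the lower ones it called 86 of the 553 and 60 of the 474. Members outside the probes fitted count here as not called. Among the probes fitted, it called 1048 of the authors' 4384 larvae against nymph calls. Each set already requires that call on the same arrays, so the overlap is not independent support.

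These overlaps join tables that share the larva or nymph arrays. With 5 unchanged groups simulated under the same sharing, between 1 and 16 transcripts met each of the 6 patterns. The simulation holds no true differences, so it does not cover probes truly changed in some comparisons that pass the others through shared arrays. Its counts are thus not a full baseline for the deposited tables. Independent lists with the observed numbers of calls would give 66.7 for larvae above all others, 53.8 for nymphs above all others, 6.87 for both stages above the 3 groups and 8.13 for both below. Part of the excess over these values may come from the shared arrays. In the same simulation between 483 and 641 of 10695 unchanged probes passed an adjusted p of 0.05 per table, with all arrays fitted as independent.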

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

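The restriction to features with a deposited fold change and every fit on the authors' probes were chosen after seeing the data, and the other alternatives before. Over all 13459 features, the 3793 calls (3002 higher in larvae, 791 in nymphs) became 6058 with all arrays as independent, with 1829 higher in nymphs, and 1370 were higher in nymphs with the biological replicate as a random block. The first arrays alone gave 506 higher in nymphs, and the technical repeat arrays alone gave 2408 calls (1931 and 477). Centring each array on its median gave 1579 higher in nymphs, and quantile normalisation gave 1746 and 1510. An adjusted p under 0.01 kept 2206 (1878 and 328). Features with a deposited fold change alone gave 1273 calls, 695 of them higher in larvae, and the authors' probes gave 1049, 513 of them higher in larvae. The authors' deposited table had 2304 higher in nymphs. Leaving out 1 biological replicate gave between 2585 and 4242 calls, between 2211 and 3095 higher in larvae and between 374 and 1147 higher in nymphs. On the authors' probes, the 1049 calls (513 and 536) became 2009 (981 and 1028) with the biological replicate as a random block, 3367 (1648 and 1719) with all arrays as independent and 356 (167 and 189) at an adjusted p under 0.01. Leaving out 1 biological replicate gave between 169 and 2739 calls there, between 87 and 1291 higher in larvae and between 66 and 1448 higher in nymphs, where the lone sample of a stage is assumed to vary like the other stage. The cause of these changes was not tested. The replicate number as a block gave 3492 calls over all features and 1017 on the authors' probes. Deviations from the stage means under equal numbers correlated at r = -0.03 over all features. Each stage gives a single contrast of replicates, so this cannot tell whether equal numbers share an origin. Requiring 2-fold in the authors' deposited tables left 1655 of 4729 probes for larvae against nymphs, 3221 for larvae and 2717 for nymphs against G, 4741 and 4796 against O, and 2214 and 2103 against S. The 4 named transcripts were chosen for the largest differences on these same arrays, so their passing of the alternatives was largely fixed by that choice. The 4 named transcripts kept their sign and stayed past the threshold in every alternative over all features and, apart from Contig4725, which was not fitted there, on the authors' probes with left-out arrays missing. Contig2438_TBP_TATA passed it with a random block (adjusted p = 0.0409, limma) and with arrays as independent (adjusted p = 0.0138, limma), within a range of 0.0138 to 0.422 over its alternatives in limma. Contig803_RiboL4 passed it in none of them. Gene lists, the filter and the variance trend on intensity, and the rule for missing values were not run, for lack of descriptions, of intensities and of missing values. At 2 replicates per stage, 8% of the 2-fold changes were recovered on simulated data with 200 of 13459 features changed. The adjustment is less strict where more features differ, and the fit of the real data called 3793. The 8% is therefore not an estimate of the share recovered in the real data.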

Other observations

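Of the tests below, those of replicate 1 against replicate 2 within a stage and of A and B probes with 1 missing member were planned before their results were seen, and the other tests of explanations after. The stage difference was compared with differences between the coded groups, which share no arrays with it. Across 10695 probes of the authors' deposited tables, larvae minus nymphs correlated with G minus O at r = -0.11, with S minus O at -0.08 and with S minus G at 0.06 (Spearman's rho -0.13, -0.05 and 0.12). Probes are not independent replicates, and no test was made. The 1018 transcripts highest in larvae had median log2 differences of 0.39 for G minus O, 0.65 for S minus O and 0.27 for S minus G. For the 712 highest in nymphs the medians were 0.82, 0.87 and 0.03. Both sets were chosen on comparisons with G, O and S, and the medians were not tested.

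The first pattern is the excess of features higher in larvae over all features, 79.1% of the calls; one shift common to every feature of an array does not account for all of it, since the features not joined had a median difference 1.90 above that of the joined ones, with a lower quartile of 1.22 against their upper quartile of 0.50. With the fit restricted to features joined to a deposited fold change the share was 54.6%, so most of the excess, but not all, lay in features not joined. It was 49.8% with left-out arrays set missing on all joined features, 49.8% with all arrays kept on the 9562 authors' probes and 48.9% with both changes. A candidate source is spots that the authors left out: over all 8 arrays, joined probes for which 1 larva array was used had a median difference 0.70 higher than those for which all 4 were used. Whether the 1.94 median difference of the features not joined may also hold transcripts truly higher in larvae cannot be told apart from weak signal without intensities.

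The second pattern is that the authors' deposited table holds more calls than the fit of biological replicates. The deposited fold changes weight technical repeats like independent arrays. On the same probes, the fit with all arrays as independent gave 3.21 times the calls of the fit of biological replicates. With the biological replicate as a random block the calls rose from 1049 to 2009. Entering repeats as independent raises the calls whatever the authors did, so the ratio does not show the source of theirs. Within a stage, 2.75% of the 6516 probes used on all arrays differed between replicates 1 and 2 of larvae beyond their technical repeats. In nymphs the share was 15.1% (limma, adjusted p under 0.05 in both stages), so the planned test was not decided. The consensus correlation in limma between the arrays of a biological replicate was 0.473 on the authors' probes and 0.305 over all features. Both are positive, so technical repeats were more alike than arrays of different replicates of a stage. The authors' table held a further 1.30 times the calls of the fit with all arrays as independent. A spread pooled over the arrays of all 5 groups may add to this, and cannot be judged without the arrays of G, O and S.

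For the calls over all features, 1 of the 3 splits of the 4 biological replicates, the real one, gave as many as 3793, and the highest other gave 0 (limma; 19 features at an unadjusted p under 0.05 in each). With 3 splits a share under 0.05 is out of reach. Each other split places a larva and a nymph replicate on both sides, so the stage difference enters its error and few calls were possible. The count of 0 therefore says nothing about chance.

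The third pattern concerns 76 contig numbers that have a probe named A and a probe named B. Over the 58 pairs with both fold changes deposited, the larvae against nymph values of A and B correlated at r = -0.00897, within the central 95% of random pairings (-0.271 to 0.250). Both members passed the authors' adjusted p in opposite directions in 7 pairs and in the same direction in 7. The letters may mark different transcripts. The remaining 18 pairs each had exactly 1 member with a fold change, but 18 is also the most that could, so that test decides nothing.

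Among the name prefixes with over 200 probes, the fold change read NA in the tables used here for 30.3% of 1516 probes starting with CK, 31.0% of 2050 starting with CV, 19.5% of 478 starting with TC, 17.0% of 206 starting with EW and 16.5% of 9121 contigs. These shares were not tested against each other.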
